A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

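The series measured RNA of 6-day-old rabbit blastocysts on 6 Agilent arrays, each carrying 2 dye-labelled samples. Per the labels, embryos had been vitrified or slowly frozen, transferred into recipient females and collected as viable 6 day embryos, and controls were untreated embryos of the same age. Vitrification is cooling fast enough, in concentrated cryoprotectant, that no ice forms; slow freezing cools at a controlled rate with ice seeded outside the embryo. Each array set 1 treated extract against 1 control extract, with 3 arrays for vitrified and 3 for frozen embryos. The treated sample carried Cy5 on the arrays of replicates 1 and 3 and Cy3 on those of replicate 2, where the dyes were swapped.

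Per the file headers, the deposited intensity values are mean pixel signals per spot in each channel with the median of the local background, made with Agilent Feature Extraction 10.10.1.1 and not normalised. Per the file headers, the deposited log10 ratio of red over green rests on signals that the scanner software had background-subtracted and dye-normalised within the array, and it was used here as an alternative. The flags for signals well above background are those of the scanner software.

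From the deposited intensities, background was corrected with the normexp method of limma 3.58.1 under R 4.3.3 with an offset of 50. Each array was normalised by loess with control spots at weight 0, and spots of the same probe were averaged. Probes well above background in at least 3 of the 12 channel measurements were tested, 30760 of 43603. The number of arrays limits the precision. A gene symbol was given to 21368 probes through the accessions, gene numbers and names in the files and a rabbit gene table of assembly mOryCun1.1. No symbol was matched for 20711 probes, 1311 matched a gene number without a symbol, and 213 matched several genes and were left unnamed. The tested probes with a symbol covered 8137 genes. The alpha globin gene of the table, HBA, stands for both alpha globin symbols of the gene list. NANOG, SOX2, CDX2, HSPA1A, HSPA8, BCL2, DNMT1, IGF2R and VEGFA, which had been chosen to be named in any case, had no tested probe with a symbol.

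The log2 ratio of treated over control was fitted per probe in limma with a coefficient for each treatment and a term for the dye over all 6 arrays, which leaves 3 residual degrees of freedom, and eBayes was applied. Adjusted p means Benjamini-Hochberg over all tested probes, with a threshold of 0.05, from limma's moderated test. The difference between vitrified and frozen embryos was the contrast of both coefficients. Values are log2 fold changes with the standard error of the fit (SE), with n = 3 arrays per treatment. An exact test of 3 against 3 samples cannot give a p under 0.1, so none was run.

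Each of 28 gene lists, fixed before the data were examined, was tested with camera at a preset inter-gene correlation of 0.01, with 1 probe per gene, the brightest. Camera with an estimated correlation and fry were run beside it. Lists with at least 5 measured genes were tested, with Benjamini-Hochberg over the lists. The lists, tests, alternatives and the rule for named genes were also fixed before the data were examined. That rule takes, per comparison and direction, the 10 genes with the largest change past the test whose direction held on all 3 arrays. Where fewer passed, it fills up to 8 with the largest changes at unadjusted p under 0.01, and these are given as values. It adds called members of each list or the list's smallest p values, the genes fixed by name, and at most 2 unnamed probes per direction. A gene that the rule takes is not reported here. Genes named outside the rule are marked as chosen after their values were seen.

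Per the labels, arrays with the same replicate number share the control extract, which pairs the vitrified with the frozen arrays. For replicates 2 and 3 the control signals of HBA differed between the paired arrays and those of TF lay closer, which leaves the sharing open. The correlation of the paired arrays' deviations from the group means was 0.020, 0.598 and 0.169 for replicates 1, 2 and 3. Replicate 2 also shares the swapped dyes. The arrays lay on 2 slides of 3 arrays each.

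The fit was tested on simulated data made from the fitted spread of 30760 probes. In the vitrified comparison it called 86.1% of 2-fold and 99.2% of 4-fold changes, with 9.9 false calls among 195.2 calls per set. In the frozen comparison it called 86.1% and 99.3%, with 9.8 false calls among 195.2. The simulated spread of a probe was drawn from the fitted prior, without regard to its change and without shared controls. In vitrified embryos HBB2 and HBA changed by more than 4-fold and did not pass. These percentages therefore do not hold for probes with a wide spread.

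The alternatives were other background, normalisation, filter, flag, dye, block, slide, spread, weight, single-channel, probe and threshold choices and leaving out each array. The spike-in probes were not used in the comparisons.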

Results

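Gene expression was measured in 6-day-old blastocysts, the stage shortly before the rabbit embryo attaches to the uterus. The 6 arrays compared 3 extracts of vitrified and 3 of slowly frozen embryos with extracts of untreated embryos. Between 44.7% and 58.0% of the spots were well above background in the green channel, and between 64.2% and 74.5% in the red. At most 11 spots on an array were saturated in the red channel.

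The first comparison asked how embryos that had been vitrified and transferred differed from untreated embryos. PSAT1, an enzyme of serine synthesis, rose 1.36 ± 0.12 (log2, SE, n = 3 arrays, adjusted p = 0.0272), and 3 of its 6 probes passed the test. Those 3 probes start between 64727049 and 64727052 and so overlap. The PSAT1 call was lost without each of the 6 arrays in turn. OTUD6A, a deubiquitinating enzyme, rose 1.46 ± 0.11 (adjusted p = 0.0272), and its control signal was well above background on 1 of the 3 arrays. The other probes that passed have no gene symbol: A_04_P034922 rose 1.69 and A_04_P006396 rose 1.11, each on 3 of 3 arrays, and the control signal of the latter was well above background on 1 of 3. The largest values of all belonged to globins, the oxygen carriers of red blood cells, and these did not pass the test.

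Counted over all probes, limma called 6 higher and 0 lower in vitrified embryos, while 5343 had an unadjusted p under 0.05 where chance gives 1538. Without vitrified replicate 2 that number was 1510. That fit takes the dye term from the frozen arrays alone, so the drop need not come from this array's values. HBB2 was at +3.61 ± 0.67 and HBA at +2.61 ± 0.38, both with an adjusted p of 0.145. SCGB1A1, the uteroglobin secreted by the rabbit uterus, was at +2.21 ± 0.31. CYP2A11 was at +1.37, RBPMS, an RNA-binding protein, at +1.30 and WFDC2, a secreted protease inhibitor family member, at +1.20. On the other side EIF4A2, a helicase of translation initiation, was at -1.12 ± 0.23 and SMG1, a kinase of nonsense-mediated decay, at -0.86. RBPJ, the transcription factor of Notch signalling, was at -0.84, JPH1 at -0.82, AP1S3 at -0.82, the nuclear import receptor IPO7 at -0.80, the caspase inhibitor XIAP at -0.79 and NDUFAF2 at -0.78. None of these fell past the test.

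**Figure D1:**
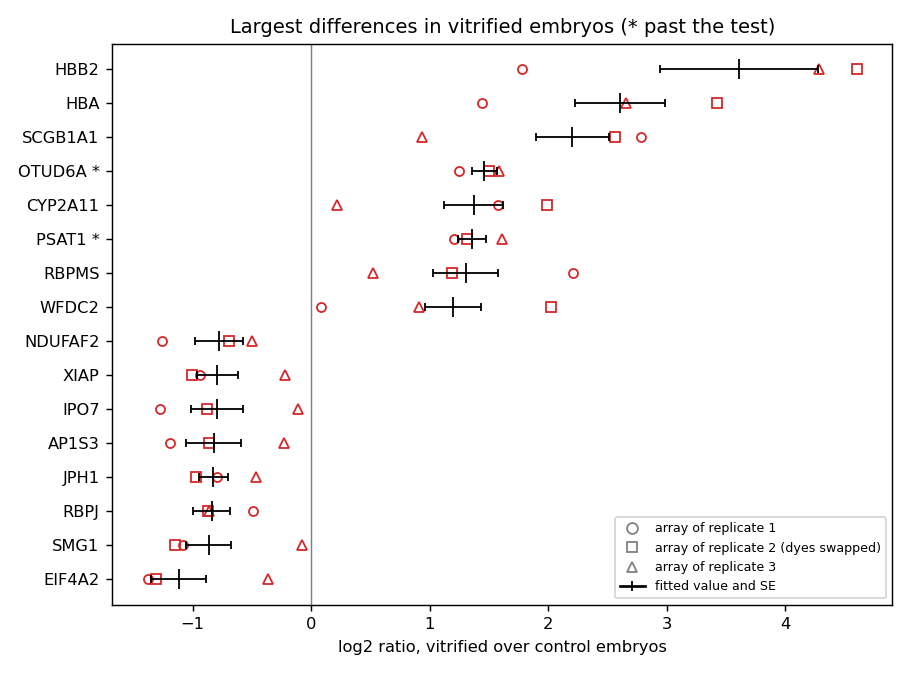
Log2 ratios of vitrified over control embryos for the genes with the largest differences. Symbols are the 3 arrays and black marks the fitted value with its SE; HBB2 is at +3.61, and the genes with an asterisk, OTUD6A and PSAT1, passed the test.

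Among the gene lists, camera called the blood and immune cell list higher in vitrified embryos, with all 10 measured genes above 0 and a median of +0.23 (adjusted p = 0.000233). It was not called with an estimated correlation (adjusted p = 0.523). Fry, which asks whether a list's genes move on balance one way, called the blood and immune list (adjusted p = 0.0303) and the extracellular matrix list (adjusted p = 0.0271) higher in vitrified embryos. None of the blood list's genes passed over all probes, and HBA and HBB2 passed when adjusted over the list alone. The trophectoderm list, genes of the outer layer that forms the placenta, had 10 of 14 above 0 and was not called (adjusted p = 0.0638). GATA2 at +0.72 and TFAP2A at +0.66 passed when adjusted over the list alone. The list of uterine epithelium and secretions was not called by camera either (adjusted p = 0.0840), and SCGB1A1 and WFDC2 passed when adjusted over the list alone. Fry's mixed test, which asks whether a list's genes change in either direction, called that list (adjusted p = 0.0149). It called 5 lists in this comparison and 0 in the frozen comparison and between the methods. Of 15 endoderm and yolk sac genes, 8 were above 0, with a median of +0.12. Without frozen replicate 2 or 3, or without vitrified replicate 2, 0 probes passed in this comparison, and 16 passed without vitrified replicate 3. A prior with an intensity trend and robust spread also gave 0, as did slide as a covariate, so PSAT1 and OTUD6A lost their calls there.

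The second comparison asked the same of slowly frozen embryos. ANXA3, an annexin that binds membranes in the presence of calcium, fell by 1.80 (SE 0.20, log2, n = 3 arrays, adjusted p = 0.0427) on all 4 of its probes. OTC, an enzyme of the urea cycle, fell by 1.34 on 3 of 3 probes. The OTC probes start between 24074602 and 24074647 and so overlap. Neighbouring ANXA3 probes, with starts of 71766766, 71766806 and 71766846, overlap in part. Within each gene these probes are not separate evidence. NID1, a basement membrane protein, fell by 1.23 on 1 of 2 probes, the other being at -0.56. OTUD6A rose 1.74 ± 0.11 (adjusted p = 0.00663), CASQ2, a calcium-binding protein of muscle, rose 1.47 ± 0.16 on 1 of 3 probes, the lowest of which was at 0.89, and NT5DC3 rose 1.32 ± 0.12; OTUD6A and NT5DC3 have 1 probe each. Genes of the endoderm and yolk sac were lower as a group, with a median of -0.51 over 15 measured genes, which was not called with an estimated correlation (adjusted p = 0.512 with an estimated correlation).

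Over all probes, limma called 27 higher and 30 lower in frozen embryos, which cover 11 genes that rose and 7 that fell. An unadjusted p under 0.05 was found for 4069 probes, and for 1087 without frozen replicate 2. The latter fit takes the dye term from the vitrified arrays alone. RTKN2 was 2.14-fold lower. MRPS15, of the mitochondrial ribosome, and the apolipoprotein APOA2 each fell by 1.00, and the secreted proteoglycan ESM1 fell by 0.99, all on each of their probes. The APOA2 probes start between 31761810 and 31761814 and the ESM1 probes between 70962881 and 70962885. They overlap within each gene and are not separate evidence. Among the genes that rose were TRPV5, a calcium channel of epithelia, at +1.16 (2 of 3 probes passed, lowest 0.40), ASZ1, a germ cell protein, at +1.12 (1 of 2, lowest 1.05) and CCNB1IP1, a meiotic factor, at +1.09 (1 of 3, lowest 0.49). TUBE1, epsilon-tubulin, was at +1.05 (1 of 3, lowest 1.01), ACSL6, which activates long-chain fatty acids, at +1.02 (4 of 5, lowest 0.91) and FBP2, an enzyme of gluconeogenesis, at +1.00 on its 1 probe. The TRPV5 probes that passed start at 9228809 and 9228839 and so overlap. ITM2A at -2.49 ± 0.61 had the largest negative value and did not pass (adjusted p = 0.168).

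Of the called probes 18 have no symbol, 12 higher and 6 lower. A_04_P034922 rose 2.22 and A_04_P006396 rose 1.56, the control signal of the latter being well above background on 0 of 3 arrays. A_04_P071512 fell by 1.76 and A_04_P102787 fell by 1.49. Of the 12 unnamed probes that rose, 7 lie on chromosome 9 between 36528078 and 36528891, as the array files give it in a build not given in the sources used here, and they rose between 0.79 and 0.88. This group was chosen after its values were seen, and most of its probes start between 36528078 and 36528082 and so overlap.

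**Figure D2:**
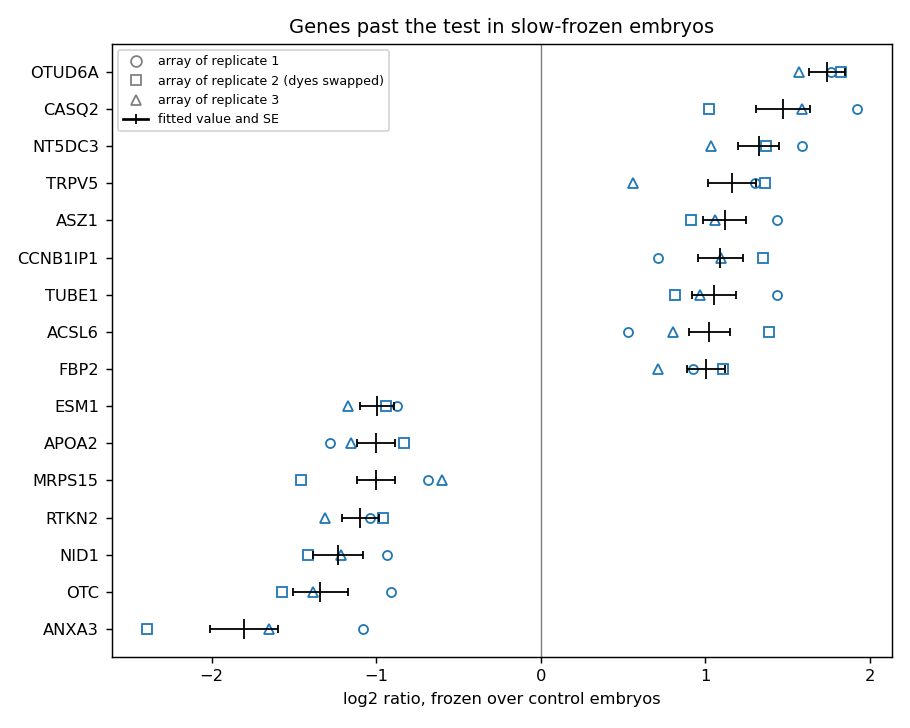
Log2 ratios of frozen over control embryos for genes that passed the test and whose probes all lay on the same side of 0. Symbols are the 3 arrays and black marks the fitted value with its SE, from -1.80 for ANXA3 to +1.74 for OTUD6A, and every array lies on the side of its fitted value.

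Camera called the endoderm and yolk sac list lower in frozen embryos, with 12 of 15 genes below 0 (adjusted p = 0.000432; adjusted p = 0.512 with an estimated correlation). Fry did not call it (adjusted p = 0.280). APOA2 fell past the test over all probes, and 7 genes passed when adjusted over the list alone, 6 lower and 1 higher. These genes, named after their values were seen, were the serum and transport proteins APOA1 at -1.13, APOB at -0.82, RBP4 at -1.25 and TF at -1.20 with FGG at -0.59, and DAB2, an endocytic adaptor, at +0.66. The list lay at -0.63 on the slide with 2 frozen arrays and at -0.24 on that with 1. Vitrified replicate 1, on the first slide, had a list median of -0.38, while the other vitrified arrays had +0.25 and +0.32. The trophectoderm list was called higher, with 11 of 14 genes above 0 and a median of +0.21 (adjusted p = 0.0212; adjusted p = 0.512 with an estimated correlation), and none of its genes passed. GATA2 was at +0.56 and GATA3 at +0.46. The trophectoderm call was lost without the filter on dim probes, without the dye term and without frozen replicate 3.

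The pluripotency list was not called (adjusted p = 0.127), and POU5F1, a core pluripotency factor, was at -0.82 ± 0.22 (adjusted p = 0.192). It passed, with TBX3, OTX2 and ETV4, when adjusted over the list alone. BMP2 at -0.95 and CER1 at -0.39, signals of gastrulation, were among 3 genes that did so in their list, all lower. That list, with a lowest value of -1.23, was not called by camera (adjusted p = 0.0891). IGF1 was at -1.06 and IGFBP5 at +0.67. HBB2 was at +1.92, HBA at +1.03 and SCGB1A1 at +1.51, none past the test. The last 2 are the brightest probes, where the vitrified values were +2.33 and +2.03; the larger vitrified values above come from other probes. The globin values rested on frozen replicate 1, where HBB2 was at 3.60 and HBA at 2.33, and without it they were 1.00 and 0.50. The number of called probes depended on single arrays: it was 1, 0 and 0 without frozen replicates 1, 2 and 3, 4 and 3 without vitrified replicates 2 and 3, and 502 without vitrified replicate 1. It was 8 without the dye term and 0 with an intensity trend and robust spread. With slide as a covariate it was 3, all higher, so ANXA3 and the other genes that fell lost their calls.

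**Figure D3:**
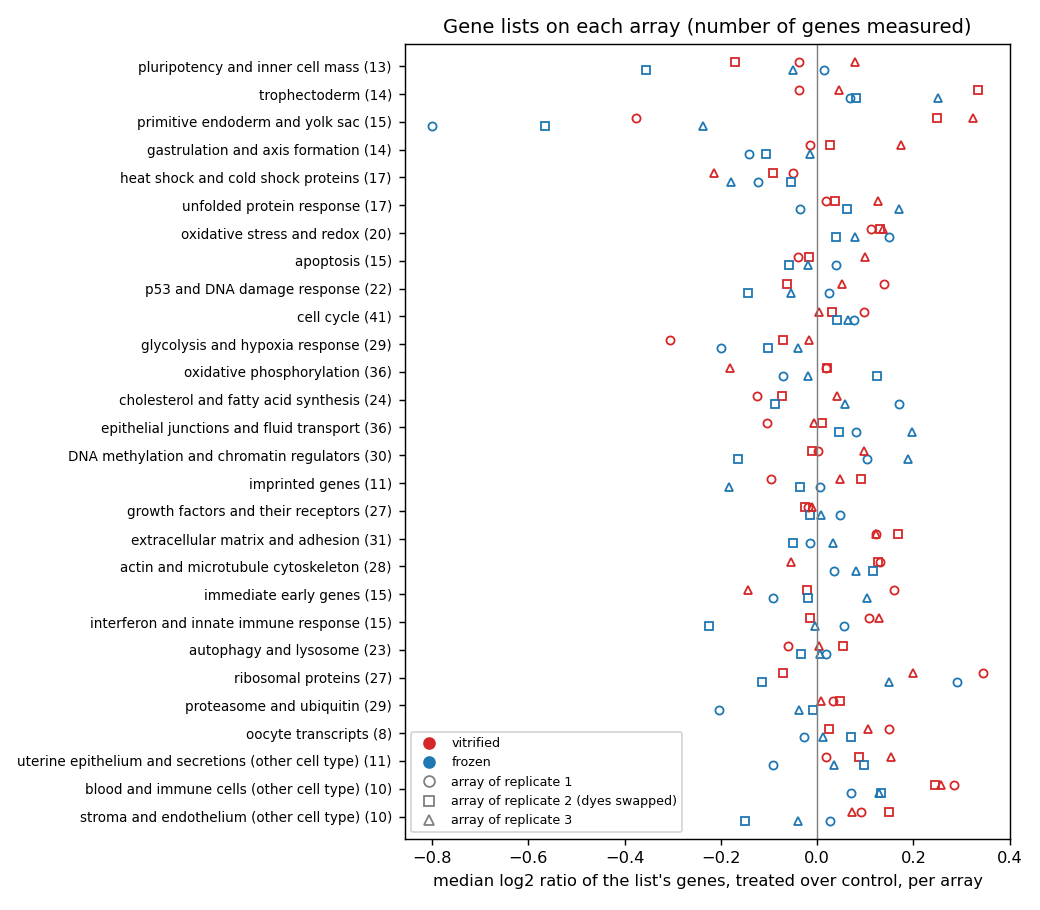
Median log2 ratio of the measured genes of each list on each array, treated over control, with the number of genes in brackets. The endoderm and yolk sac list runs from -0.80 on frozen replicate 1 to +0.32 on vitrified replicate 3.

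The third comparison set the vitrified against the frozen embryos. The log2 difference of vitrified minus frozen was +1.77 ± 0.32 for PSAT1, +1.30 for PHGDH, which starts serine synthesis, and +1.17 ± 0.16 for APOA2. The PSAT1 value is from its brightest probe, which was not called in vitrified embryos (+1.52, adjusted p = 0.145), and its 6 probes ran from 1.15 to 1.77. TRPV5 was at -1.40 ± 0.19 (-0.34 on its least changed probe), ANGPTL4, a regulator of lipoprotein lipase, at -1.10 and HADHA, of fatty acid oxidation, 2.00-fold lower by its fitted value. None of these passed the test, in which the smallest adjusted p was 0.224.

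Limma called 0 probes between the methods, with 2320 at an unadjusted p under 0.05. UBE2S was at +1.56, SCGB1A1 at +1.52 (+0.52 on its brightest probe), the troponin TNNC1 at +1.41, LIX1 at +1.33 and ANXA3 at +1.20. ASZ1 was at -1.09, PRXL2A at -0.94, RBBP7 at -0.92, the drug transporter ABCB1 at -0.91 and FBP2 at -0.86. Camera called 5 lists, and fry called the extracellular matrix list alone (adjusted p = 0.0350). The endoderm and yolk sac list was higher in vitrified embryos, 13 of 15 genes above 0, median +0.62 (adjusted p = 2.5e-05; adjusted p = 0.543 with an estimated correlation), APOA2 passed when adjusted over the list alone, and fry did not call the list (adjusted p = 0.445). The blood and immune list had all 10 genes above 0 (adjusted p = 0.0192; adjusted p = 0.543 with an estimated correlation). Cholesterol and fatty acid synthesis was lower at a median of -0.11 (adjusted p = 0.0304; adjusted p = 0.648 with an estimated correlation), with ACSL1 at -0.61. Extracellular matrix was higher at +0.10 (adjusted p = 0.0436; adjusted p = 0.543 with an estimated correlation), with NID1 at +0.71. Junctions and fluid transport was lower at -0.08 (adjusted p = 0.0471; adjusted p = 0.543 with an estimated correlation), with CLDN3, a tight junction protein, at -0.81, and its adjusted p was 0.0508 with the replicate number as a random block. For the difference between methods, leaving out either replicate 2 array gives the same fit. The endoderm list kept its call without each array in turn. The blood list lost it without vitrified replicate 1, the cholesterol list without vitrified or frozen replicate 1, and the matrix and junction lists without replicate 1 or 3 of either treatment. Within slides the endoderm difference was 0.15 on slide 1 and 0.80 on slide 2.

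**Figure D4:**
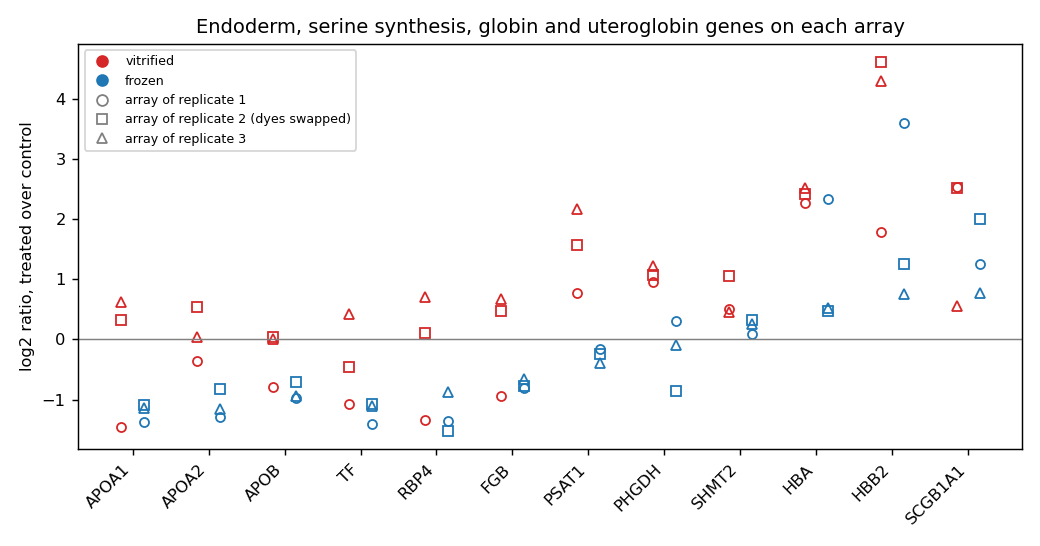
Log2 ratio of treated over control on each array for endoderm, serine synthesis, globin and uteroglobin genes, each by its brightest probe. PSAT1, by a probe that was not called, lies between 0.78 and 2.17 on the vitrified arrays and below 0 on the frozen arrays; these genes were chosen after their values were seen.

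Finally, both treatments were compared in their fold changes over all probes. OTUD6A, A_04_P034922 and A_04_P006396 rose in both, 3 probes where independent lists give 0.0053 and unchanged groups simulated against the same control extracts give 0.04 on average, and 0 fell in both. Those simulated groups had 0.26 calls on average in the vitrified and 0.54 in the frozen comparison, against 6 and 57 here. With so few calls an overlap near 0 was fixed in advance, so the 0.04 is no baseline for the 3 shared probes. Per the labels, both treatments also shared transfer into recipients, and the controls were untreated. A rise in both therefore cannot be told apart from an effect of transfer. Of the probes higher in frozen embryos 18 of 27 were also above 0 in vitrified embryos, and of those lower 25 of 30 were below 0; for as many top probes, the unchanged groups gave 25.3 and 28.0. The fold changes correlated at r = 0.533 across 30760 probes, which are not independent replicates. Unchanged groups simulated against the same control extracts gave 0.543, with all of the residual spread placed equally in the treated and control extracts. That setting makes same-numbered arrays resemble each other, while their fitted correlation within replicate numbers was -0.10. The simulated values, 25.3 and 28.0 included, may therefore overstate what shared controls give, and they do not decide whether the treatments agree. The simulation takes the shared extracts from the labels, and the HBA control signals of replicates 2 and 3 differed between the arrays said to share them. The covariance was 0.0299 against 0.00938 simulated, a difference of 0.0205. The same sign held for 64.4% of probes against 68.3% simulated. The 3 control extracts cannot be split into groups of at least 2, so part of the excess may come from the shared controls. Among arrays of the same dye orientation, pairs of replicates 1 and 3 with a shared control had a mean covariance of 0.0323 and pairs without one 0.0412. Without vitrified replicate 1 the correlation was 0.343.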

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

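The tests of explanations and the splits in this part were chosen after the results were seen; the list tests and the fits without single arrays were not. There were 6 results to look at, 5 of them between the treatments found by the test of the difference itself, and 1 in the spike-in probes, which no comparison used.

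The endoderm and yolk sac genes differed by a median of 0.62 between vitrified and frozen embryos, being lower in frozen than in control embryos. Against dye bias, the median on the dye-swapped frozen array was -0.57, below 0 as on the other frozen arrays. Its bootstrap interval, from resampling the list's genes within that array, ran from -0.78 to -0.37. Such an interval treats the genes as independent and holds no spread between arrays, so this argument rests on 1 array. A single frozen array is also argued against, since the highest adjusted p of the list in fits that each left out 1 frozen array was 0.0371, though over all arrays the list was not called with an estimated correlation. A difference between slides stays open: the frozen array on the second slide lay at -0.24 with an interval from -0.93 to 0.21. A smaller share of endoderm cells could also give the pattern and was not excluded, although DAB2 stood at 0.66. The freezing itself stays open. Per the labels, transfer and the collection of viable embryos went with cryopreservation. Against the untreated controls these cannot be told apart.

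The blood and immune list differed by 0.25, with HBA and HBB2 highest in vitrified against control embryos. Dye bias of the globin probes is argued against by the dye-swapped vitrified array, where the lower of both ratios was 2.43. Blood cells carried over when embryos were collected may be the source, and ALAS2, another red cell gene, was at 0.75 (SE 0.25, adjusted p = 0.218), which does not decide it. The 7 measured leukocyte genes had a median of 0.16.

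The spike-in log2 ratios spanned 0.48 on frozen replicate 1 against 5.26 to 5.92 on the other 5 arrays, and frozen replicates 2 and 3 ran opposite to the vitrified arrays, with slopes of -1.02 and -0.94 on vitrified replicate 1. Vitrified replicate 1 correlated at a mean of 0.450 with the other frozen arrays and 0.331 with its own group, the highest such mean among the vitrified arrays. An exchange of the labels of the 2 arrays numbered 1 could not be told apart from other causes, as frozen replicate 1 correlated with the other vitrified arrays by -0.080 relative to the other frozen arrays. The spike-in ratios of vitrified replicate 1 ran with those of vitrified replicates 2 and 3 (r = 0.992 and 0.997). Vitrified replicate 2 has swapped dyes and still ran the same way in red over green. These ratios therefore cannot tell which embryos' RNA an array carried. The endoderm list median of frozen replicate 1 was -0.80. That frozen replicate 1 carried RNA of no frozen embryo stays open as well: 65 of the 100 probes with the smallest p without it moved the same way on it, with a median of 0.14, against a median absolute change of 1.03 without it. The probes were picked in the fit that gave the 1.03, which raises that value. No other array was checked in this way, so the gap does not set this array apart.

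The cholesterol and fatty acid synthesis list differed by -0.11. The extracellular matrix list differed by 0.10. The junction and fluid transport list differed by -0.078.

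Among the 4 splits per comparison, the real one and the 3 that exchange treated and control on single arrays, 1, the real one itself, gave as many probes in the vitrified comparison (6, highest other 0) and likewise 1 in the frozen (57, highest other 0). For lists, with the real one counted, 2 of 4 gave as many in the vitrified comparison (1, highest other 3) and 2 of 4 in the frozen (2, highest other 2). Between the methods the real count of 0 probes is reached by any split, 10 of 10, which says nothing on chance (highest other 7, from the split exchanging the arrays numbered 1, which parts all pairs), and 2 of 10 gave as many lists (5, highest other 5). The other split with 5 lists follows the slides, and within slides 1 and 2 the median differences were 0.15 and 0.80 for the endoderm list, 0.27 and 0.18 for blood, 0.14 and 0.12 for matrix, -0.21 and -0.10 for cholesterol, and -0.11 and -0.12 for junctions. These splits are too few for a share under 0.05.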

How the results depend on the processing

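The 3 probe counts and 3 list counts were each recomputed under the alternatives fixed in advance for them; the cause was not tested. Array weights, separate channels, slide as a covariate, the trend and robust prior and the fits of each comparison alone were run for probe counts and not for lists. The separate-channel fit treats control channels of the same extract, per the labels, as independent. The array weights rest on 3 residual degrees of freedom and were 2.85 on both dye-swapped arrays, the highest. The large counts of these fits may therefore overstate what changed. Vitrified against control (6 probes) gave 0 with the scanner software's ratios, 0 with scaling between arrays, 0 with the strict filter, 0 with slide as a covariate and 0 with trend and robust prior. It gave 3575 with array weights, 2358 with separate channels, 1 with 1 probe per gene and 89 at p under 0.01 with 2-fold. Leaving out single arrays gave 0 to 16. Frozen against control (57) gave 1 with the scanner software's ratios and 33 with median centring, 8 higher and 25 lower. It gave 105 with scaling, 8 without the dye term, 3 with slide as a covariate and 0 with trend and robust prior. It gave 5572 with array weights, 12 fitted alone, 860 with separate channels, 17 with 1 probe per gene, 187 at adjusted p under 0.10 and 121 at p under 0.01 with 2-fold; leaving out single arrays gave 0 to 502. Vitrified against frozen (0) gave 1137 with array weights, 81 with separate channels and 45 at p under 0.01 with 2-fold, and 0 to 0 without single arrays. The list counts (1, 2 and 5) were 0, 0 and 0 with an estimated correlation. In vitrified embryos 2 lists were called with no background subtraction, 3 with median centring and 3 with the mean over probes. In frozen embryos 1 was called without the filter and 1 without the dye term, and between methods 3 with the strict filter. Leaving out single arrays gave 1 to 8, 2 to 4 and 2 to 5 lists. The correlation of fold changes ran from 0.488 to 0.537 over the background, normalisation, filter, flag and dye alternatives, the others not being run for it, and from 0.343 to 0.591 without single arrays. The random replicate block gave 8, 61 and 0 probes and 1, 2 and 4 lists, and the fixed replicate block 0 probes and 6 lists between methods; neither moved a count by over 1.5 times. Between methods the endoderm list was called in 18 of 18 settings, estimated correlation aside. Leaving out vitrified replicate 2 or frozen replicate 2 gives the same fit there, so these settings are not separate. The blood list was called in 16 of 18 (lost with the strict filter), the cholesterol list in 14 (lost with the scanner software's ratios and the strict filter) and the matrix list in 13 (lost with the mean over probes). The junctions list was called in 8, and was also lost with no background subtraction, the scanner software's ratios, either filter and the random replicate or slide block. With 1 array left out, the pooled spread is assumed to hold for the remaining arrays. Without a replicate 2 array, the dye term comes from the arrays of the other treatment alone. Of the named genes, 298 of 531 called values stayed past the test and 233 did not, with 0 changes of direction; of 4362 uncalled values 235 passed and 7 changed direction. Probes near background limit the dim genes, and 19074 probes were above it in all channels.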

Other observations

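PHGDH, SHMT2, the list members named here and the control signals of HBA, TF and HBB2 were picked after their values were seen. The limma and list tests were fixed in advance. Beside PSAT1, other enzymes of serine metabolism had no fixed list and no enrichment test: in vitrified embryos PHGDH was at +1.00 ± 0.16 and SHMT2 at +0.74 ± 0.11, neither past the test (adjusted p = 0.145 each). In frozen embryos they were at -0.30 and +0.28. In vitrified embryos the unfolded protein list was not called by camera (adjusted p = 0.0840) but was called by fry's mixed test (adjusted p = 0.0198). In that list 5 genes passed when adjusted over the list alone: PDIA4 at +0.80, CHAC1 at +0.57, SEL1L at +0.43, CALR at +0.42 and ATF6 at +0.34. The actin and microtubule list was not called (adjusted p = 0.379), and S100A11 at +1.16, PFN1 at +1.09, ACTN1 at +0.81 and S100A10 at +0.46 with ACTR2 at -0.62 passed when adjusted over the list alone.

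The heat shock and cold shock list was not called in vitrified (adjusted p = 0.199) or frozen embryos (adjusted p = 0.132), with medians of -0.10 and -0.11. The chromatin list was not called in vitrified embryos (adjusted p = 0.940), where TRIM28 at +0.84 and EHMT2 at +0.54 passed when adjusted over the list alone.

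The HBA signals of control extracts 1, 2 and 3 were 10.34, 12.56 and 11.14 (log2, mean intensities quantile-normalised between arrays) on the vitrified arrays. On the frozen arrays they were 10.48, 10.33 and 9.50, though the labels give the same extracts. The TF signals of control extracts 2 and 3 were 13.08 and 12.33 on the vitrified and 12.97 and 12.17 on the frozen arrays. Those of HBB2 were 12.37 and 11.28 against 11.51 and 10.82. HBA differed more than TF or HBB2, and so few genes cannot decide whether the extracts were shared.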
